A study of Mus musculus with 4 samples.

How the data were processed

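RNA from the dorsal dermis of mouse embryos at embryonic day 15.5 was measured on 4 Affymetrix Mouse Genome 430 2.0 arrays, with 2 arrays labelled control and 2 labelled mutant. The mutant embryos carried a Cre recombinase under the keratin 14 promoter, which is active in surface epithelium, and a Ctnnb1 allele from which Cre removes an exon. The protein made after that deletion, beta-catenin, escapes degradation, so the epithelium carries activated Wnt signalling while the dermis beneath it is not the targeted tissue. The skin was treated with dispase, an enzyme that parts epidermis from dermis, and RNA was taken from the dermis, per the labels' protocols. The controls were littermates, per the labels. An array hybridises biotin-labelled RNA to short probes, and a probe set is the group of probes that reports a transcript.

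The deposited values are signal intensity per probe set on a linear scale. GCOS and MAS5 are named for them per the submitters' processing notes, and their versions, the background handling and the detection calls are not given in the sources used here. The deposited intensity values had been scaled per array, since the mean after trimming 2% of probe sets at each end was 150.0 on all 4 arrays. The median signal was 29.8 on the array labelled control 1, 29.8 on control 2, 28.7 on mutant 1 and 32.4 on mutant 2. No further normalization was applied. An array carries no read depth, and its precision here is limited by the number of arrays.

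A second deposited table lists 153 probe sets that the authors called changed, each with a fold, the ratio of normalized mutant to control levels, per the file headers. The headers name GCRMA normalization, detection on at least 2 of 4 arrays, an uncorrected test with p under 0.01 and a fold of 2, so the authors' table rests on values processed differently from the deposited signals. Its columns per embryo, also ratios set by the authors relative to control, gave a mutant over control ratio within 10% of the listed fold for 2 of the 153 probe sets and on the same side of 1 for 96. Those columns were not used further. The listed probe sets were selected by the authors from the same 4 arrays, so the table is not independent evidence of any direction. From the deposited instrument records of each array, the fluidics module, the order and day of scanning and the shared hybridization were used. Those records name the sample type as mouse epidermis on all 4 arrays, whereas the labels say dermis.

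The table of values holds 45101 probe sets, of which 64 are array controls that were left out. The platform annotation gives 1 gene for 34958 probe sets, several for 932 and none for 9211. Symbols were looked up through the gene number in a table of the GRCm38.p6 assembly for 34754 probe sets, and 0 symbols changed. The probe sets name 18194 genes. No coordinates are given because no genome was used. A gene is represented by its probe set with the highest mean over the 4 arrays, among probe sets that name that gene alone. Probe sets of keratin-associated protein genes can bind transcripts of near-identical paralogs, and the identity of the family member is uncertain.

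The comparison of mutant with control used limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3 on log2(signal + 16), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Differences on this scale understate the change of dim probe sets. Probe sets with a mean log2 value at or above the median, 5.515, were tested, which left 22519 probe sets naming 11413 genes. On simulated data of the same 22519 probe sets, with 200 changed, the test recovered 0% of 3-fold changes and 79.5% of 10-fold changes, the latter with 4 false calls. The simulated noise was independent between probe sets, while the measured arrays share a structure across probe sets. These figures therefore hold for independent noise and may not hold for the measured arrays. Gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, over the 23 of 24 lists that had at least 4 tested members. Enrichment of the authors' list in the fixed lists was tested with Fisher's exact test, two-sided, against the 11413 tested genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures.

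The main test, the gene lists, the rule for named genes and most alternatives were set before the data were examined. The rule took the 12 genes with the largest differences in each direction among those past the threshold. Where fewer passed, it took the largest differences of genes whose mutant arrays lay on one side of both controls. It added up to 2 further members of each list with the largest difference either way, Ctnnb1 and Krt14, the sex-linked genes, and the 5 highest and 5 lowest folds of the authors' table. Other genes named in the text were chosen after their values were seen. The alternatives were other pseudocounts, other scalings, other filters, the replicate number as a block, each array left out in turn, and other forms of each test. A t-test with unequal variances, at the p under 0.01 and fold of 2 named with the authors' table, is called the methods' t-test. It and a crossed pairing were added after the data were seen. A block for scanning date was not run because all 4 arrays were hybridised together and scanned on the same day.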

Results

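The data comprised 4 arrays of dermal RNA from mouse embryos, with 2 arrays labelled mutant and 2 labelled control. The study asked how the dermis differed beneath an epithelium with activated beta-catenin, the transducer of canonical Wnt signalling. The scaled mean signal was 150.0 on every array, and the ratio of 3' to 5' signal for Actb, a measure of RNA integrity, lay between 1.16 and 1.22. The labels give separate embryos for each group. The p-values of fits to all 4 arrays rest on 2 arrays per group, and those without an array on 1 against 2. Camera at the preset correlation is an exception. Its p-values weigh a list against the spread between genes and do not measure the spread between embryos. Fisher's exact test rests on counts of genes. Arrays are named throughout by their labels, and the authors' deposited table goes against those labels.

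Ctnnb1, the gene altered in the mutant, gave signals of 5335 and 4721 on the arrays labelled control 1 and control 2 and of 4838 and 4397 on those labelled mutant 1 and mutant 2. Its log2 difference was -0.12 ± 0.14 (SE, n = 2 per group), with a limma adjusted p of 0.9999. Whether its probe sets lie in the deleted exon is not known here, and the allele is altered in epithelium and not in dermis, so the value does not check the labels. Krt14, the basal keratin whose promoter drives Cre, gave 112 and 79.7 on the control arrays and 247 and 140 on the mutant arrays, with a limma adjusted p of 0.9999. The Y-linked genes Eif2s3y, Kdm5d and Uty gave 524, 224 and 86.6 on the array labelled mutant 1. Each lay at 7.23 or below on the other 3 arrays. Xist, the RNA that silences an X chromosome in females, gave 11.4 on mutant 1 and 3836, 3512 and 3108 on control 1, control 2 and mutant 2. These are the signals of male tissue on mutant 1 and of female tissue on the other 3 arrays.

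The authors' deposited table lists 97 probe sets as higher and 56 as lower in mutant. The 5 highest folds in the authors' deposited table belong to Krtap8-1 (1220), Krt2-18 (428), Krtap7-1 (322), Krtap16-3 (307) and Gm10229 (274), the last listed there as Krtap6-1. Krtap genes encode matrix proteins of the hair shaft. The 18 hair keratin and keratin-associated probe sets, a family picked after the values were seen, were all listed as higher in the authors' deposited table, by 6.10 to 1220 times. The 5 lowest values in the authors' deposited table belong to Irx2 (0.01), Tmem87a (0.0101), Nt5e (0.0151), Tmem150c (0.0163) and Irx1 (0.0168). With its direction turned, the authors' deposited table would list 56 as higher and 97 as lower, with Irx2 the highest at 100 and Krtap8-1 the lowest at 0.001. A turned table would not follow the array labels either, because the mismatch described below is one of grouping. Irx1, Irx2 and Irx3 are Iroquois homeobox transcription factors, and Irx3 is listed at 0.0743 in the authors' deposited table.

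Signalling genes in the table went both ways, and those named here were chosen after their values were seen. The authors' deposited table lists as higher the homeobox gene Dlx2 (87.2), the BMP ligand Bmp5 (12.3), the Hedgehog antagonist Hhip (20.9) and the Wnt antagonist Frzb (7.09). It also lists as higher Smad6 (4.61) and Smad7 (4.56), which restrain BMP and TGF-beta signalling, and the Notch target Hey1 (2.85). The authors' deposited table lists as lower the Wnt agonist Rspo1 (0.0268), the Wnt antagonists Sfrp5 (0.0191) and Apcdd1 (0.216), the ligand Wnt4 (0.287) and the retinoic acid binding protein Crabp1 (0.0934). BMP response genes, a list fixed in advance, held 3 of the table's genes, Atoh8, Smad6 and Smad7, among 14 tested members, where 0.144 was the number by chance (odds ratio 26.9, Fisher's exact test, adjusted p = 0.00845 over 24 lists). No other list passed this test, and because the table was chosen on these arrays the count is not independent evidence of its direction.

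The directions in the authors' deposited table did not follow the array labels. Krtap8-1 gave signals of 1237 on the array labelled control 1 and 1369 on mutant 2, but 8.01 on control 2 and 3.21 on mutant 1. Across the 18 hair keratin and keratin-associated probe sets, signals ran from 92.2 to 1237 on control 1 and from 86.1 to 1369 on mutant 2. They lay at 22.1 or below on control 2 and at 11.6 or below on mutant 1. Irx1, Irx2 and Irx3 gave 409 to 638 on control 2 and 367 to 624 on mutant 1, against 28.9 to 85.3 on control 1 and 29.1 to 93.8 on mutant 2. Of the 97 probe sets that the authors' deposited table lists as higher, 96 had both control 1 and mutant 2 above the other pair of arrays, and all 56 listed as lower had them below. For 0 of the 153 did both arrays labelled mutant lie on one side of both labelled control.

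**Figure D1:**
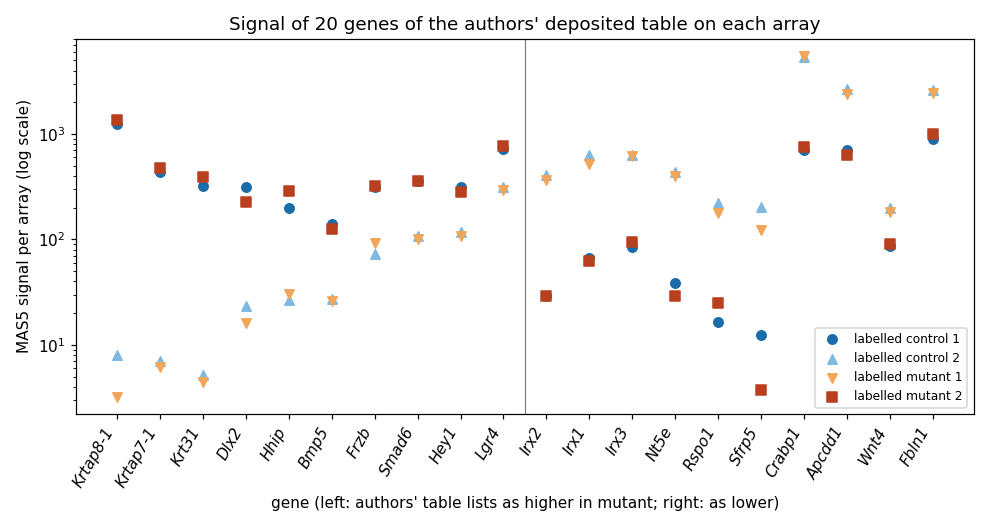
Signal of 20 genes of the authors' deposited table, chosen after their values were seen, on each of the 4 arrays, on a log axis, with 1 point per array and no averaging. For each gene the points of control 1 and mutant 2 lie together, and so do those of control 2 and mutant 1, as for Krtap8-1 at 1237 and 1369 against 8.01 and 3.21.

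With the arrays taken as labelled, the log2 difference of mutant minus control had the direction of the authors' deposited table for 80 of 153 probe sets (52.3%), and it lay between -0.59 and 0.50 for all of them. The corresponding log2 folds in the authors' deposited table run from -6.64 to 10.3. Across these probe sets, which are not independent, the correlation between both was 0.10 (Pearson) and 0.12 (Spearman). Leaving out the array labelled control 1 or mutant 1 brought the share to 98.7% or 99.3%, and leaving out control 2 or mutant 2 to 0.654% or 1.31%. A direction below is therefore that of the array labels alone, and a direction in the authors' deposited table is that of the table alone.

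**Figure D2:**
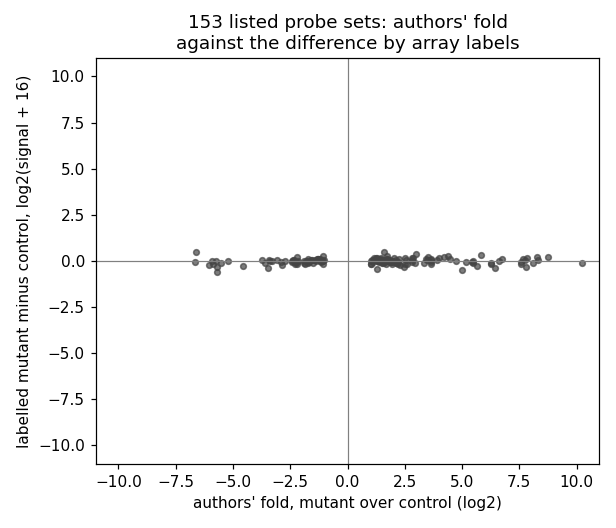
Each point is 1 of the 153 probe sets of the authors' deposited table, with the log2 of the authors' fold on the horizontal axis and the log2 difference between arrays labelled mutant and control on the vertical axis. The differences by label lie between -0.59 and 0.50 while the authors' log2 folds span -6.64 to 10.3.

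Between the arrays labelled mutant and those labelled control, 0 of 22519 probe sets passed the threshold in limma, fitted without a block, and 208 had an unadjusted p under 0.05, where 1126 would by chance. The methods' t-test with a 2-fold difference gave 3 probe sets, Fabp3, Anxa8 and an unnamed one, and 0 after Benjamini-Hochberg adjustment. Both labelled mutant arrays lay on one side of both controls for 20.5% of probe sets, where chance gives 33.3%. The genes below are therefore given as values, each with a limma adjusted p of 0.9999 in that fit.

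Among genes whose arrays labelled mutant both lay above both labelled control, the largest differences included cartilage, muscle and epidermal genes. Without that condition the list members Matn1 and Col2a1 differed by more, at 2.97 ± 1.91 and 2.91 ± 2.32. Comp, a cartilage matrix protein, differed by 2.55 ± 1.43, Cnmd by 2.33 ± 1.40 and Col11a2 by 1.79 ± 0.98 (log2, SE, n = 2 per group). All 3 rested on the array labelled mutant 2, where Comp gave 746 against 9.77, 14.1 and 19.1 on control 1, control 2 and mutant 1. The muscle genes Sln, Csrp3, Tnnc1 and Mylpf differed by 1.76, 1.76, 1.54 and 1.30, and Tceal7 and Cox8b by 1.74 and 1.51. These 6 genes had their highest signal on mutant 1 and their lowest on control 1, as for Sln at 963 and 81.4. Fam25c, Lgals3 and Calm4 differed by 1.45, 1.38 and 1.36, and Lgals3, which encodes galectin-3, gave 68.3 and 54.4 on the control arrays and 158 and 217 on the mutant arrays. Without 1 array, 11 of these 12 genes moved by over 1.5 times, such as Comp (0.33 to 4.77), Sln (0.91 to 2.61), Mylpf (0.55 to 2.04), Fam25c (0.69 to 2.21) and Calm4 (0.81 to 1.91), while Lgals3 ran from 1.17 to 1.59.

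Among genes whose arrays labelled mutant both lay below both labelled control, the largest difference was that of Xist, -3.66 ± 2.19. It rested on mutant 1, the array with male signals, and so follows embryo sex. Smim10l1 followed at -1.13 ± 0.15, with 844 and 682 on the control arrays and 336 and 339 on the mutant arrays, but the other 2 probe sets of Smim10l1 went the other way. The other named differences were smaller, at -0.79 for Zfp949, -0.75 for Gkn3, -0.70 for Fzd10os, -0.67 for Arl2bp and -0.64 for Pyroxd1. Borcs8 differed by -0.61, while Zfp689, Pcp4l1, Hbb-b2 and Ccl3 each differed by -0.60. Without 1 array, 5 of these 12 genes moved by over 1.5 times: Xist (-7.07 to -0.24), Zfp949 (-1.10 to -0.49), Pyroxd1 (-0.86 to -0.41), Borcs8 (-0.87 to -0.35) and Ccl3 (-0.98 to -0.21). Leaving out the array labelled mutant 2 gave 1 probe set past the threshold, that of Xist (limma adjusted p = 0.0436).

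Of the gene lists fixed in advance, 6 passed at the preset correlation, led by skeletal muscle and epidermis, and 0 of the 6 passed with an estimated correlation. A marker is called higher or lower by the mean of the 2 arrays of each label. All 17 skeletal muscle markers had the higher mean on the arrays labelled mutant, though both of these arrays lay above both labelled control for only 2, and the median log2 difference was 1.08 (camera, adjusted p = 8.72e-13 at the preset correlation, adjusted p = 0.941 with an estimated correlation). The fast troponin Tnnt3 gave 98.5 and 326 on control 1 and control 2 and 859.5 and 307 on mutant 1 and mutant 2, and the creatine kinase Ckm differed by 1.39. Without control 1 the muscle call ended (adjusted p = 0.138, median 0.28), and the median was 1.82 without control 2 and 0.56 without mutant 1.

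Epidermal keratinocyte markers were higher for 16 of 17, for 9 of them on both arrays, with a median of 0.88 (camera, adjusted p = 1.79e-12 at the preset correlation, adjusted p = 0.941 with an estimated correlation). The cornified layer genes Krtdap and Lor gave 763 and 619 on mutant 1 and no more than 64.4 and 76.0 on the other arrays. Without mutant 1 the epidermal call ended (adjusted p = 0.13, median 0.38). Cartilage and bone markers were higher for 7 of 8, for 0 of them on both arrays, with a median of 1.89 (camera, adjusted p = 0.00792 at the preset correlation, adjusted p = 0.941 with an estimated correlation). Col2a1, the main collagen of cartilage, gave 2857 on mutant 2 and 17.2 or less elsewhere, and Matn1 gave 1284 there and 7.45 or less elsewhere. The cartilage call ended without control 2 (adjusted p = 0.283, median 1.15), the median turned to -0.72 without mutant 2 (adjusted p = 0.0508), and it was 4.30 without mutant 1.

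Endothelial markers were lower for 12 of 14, for 8 of them on both arrays, with a median of -0.18 (camera, adjusted p = 2.73e-06 at the preset correlation, adjusted p = 0.941 with an estimated correlation), as for the VEGF receptor Kdr at -0.37 and the lymphatic receptor Lyve1 at -0.57. The endothelial median was -0.11 without mutant 1 (adjusted p = 0.0329). Cell cycle genes were lower for 16 of 18 by a median of -0.08 (camera, adjusted p = 0.0229 at the preset correlation, adjusted p = 0.941 with an estimated correlation), with Plk1 at -0.28 and Aurkb at -0.17. The cell cycle call ended and its tested direction turned without control 2 (adjusted p = 0.972, median -0.03) and without mutant 2 (adjusted p = 0.636, median 0.0495), and the median was -0.15 without control 1 and -0.17 without mutant 1. Immediate early and heat shock genes were lower for 8 of 12 by a median of -0.10 (camera, adjusted p = 0.0229 at the preset correlation, adjusted p = 0.941 with an estimated correlation), with Ier2 at -0.38 and Dusp1 at -0.32. The immediate early call ended without control 1 (adjusted p = 0.956, median turned to 0.0277) and without mutant 1 (adjusted p = 0.742), and the median was -0.22 without control 2 and -0.24 without mutant 2. With fry none of the 6 lists passed (adjusted p = 0.96), and no member of any list passed in limma, over all probe sets or adjusted over the list alone.

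The signalling lists did not pass by label in the unblocked fit of all 4 arrays. A crossed block paired control 1 with mutant 2 and control 2 with mutant 1. With it, the Wnt response list passed as lower by a median of -0.05 (camera, adjusted p = 0.0304 at the preset correlation). That pairing was picked from these data, so the call is not independent evidence. Wnt response genes were higher for 5 of 19 (Dkk1 -0.56 ± 1.06, Lef1 -0.31 ± 0.33) and BMP response genes for 5 of 14 (Bmper 0.75 ± 0.99, Atoh8 0.50 ± 0.64). Dermal condensate and papilla genes, the mesenchyme of hair follicles, were higher for 14 of 26 (Rspo2 0.64 ± 1.62, Alpl 0.49 ± 0.96). Hedgehog targets were higher for 2 of 9 (Mycn -0.37 ± 0.17, Hhip 0.26 ± 1.21) and FGF response genes for 3 of 10 (Spry4 -0.35 ± 0.22, Spry1 -0.16 ± 0.14). Notch response genes were higher for 4 of 11 (Jag2 0.17 ± 0.21, Dll1 0.16 ± 0.45), retinoic acid pathway genes for 6 of 7 (Cyp26b1 -0.34 ± 0.22, Dhrs3 0.23 ± 0.38) and hair placode markers for 6 of 7 (Bmp2 0.58 ± 0.54, Madcam1 -0.34 ± 0.28). The adjusted p of the 17 lists that did not pass ran from 0.0884, for Hedgehog targets, to 0.956, for pericytes (camera). At the preset correlation, BMP response genes passed whenever an array was left out, higher without control 1 (median 0.51, adjusted p = 0.000262) and mutant 1 (0.41, adjusted p = 0.0329) and lower without control 2 (-0.74, adjusted p = 3.65e-06) and mutant 2 (-0.62, adjusted p = 0.00438). An estimated correlation was not run without an array, and with all 4 arrays BMP response genes had adjusted p = 0.961 with an estimated correlation. Hedgehog targets passed at the preset correlation as lower without mutant 2 (median -0.30, adjusted p = 0.0118), and with all 4 arrays had adjusted p = 0.941 with an estimated correlation.

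Markers of other dermal cell types did not pass by label in the unblocked fit either. With the crossed block picked from these data, the adipocyte and the Schwann cell and nerve lists passed as higher, by medians of 0.20 and 0.14. Adipocyte markers were higher for 7 of 7 (Car3 1.36 ± 1.93, Adipoq 1.15 ± 2.43), fibroblast and matrix genes for 12 of 25 (Mfap5 1.04 ± 0.81, Mfap4 0.34 ± 0.12) and pericyte markers for 5 of 10 (Cspg4 0.41 ± 0.29, Pdgfrb -0.29 ± 0.20). Erythroid markers were higher for 4 of 5 (Hbb-y -0.38 ± 0.49, Hbb-bh1 0.20 ± 0.41), leukocyte markers for 4 of 16 (Aif1 0.27 ± 0.24, Laptm5 -0.26 ± 0.17) and mast cell markers for 2 of 7 (Hdc -0.17 ± 0.24, Kit -0.16 ± 0.14). Schwann cell and nerve markers were higher for 7 of 10 (S100b 0.62 ± 1.08, Nefl 0.56 ± 0.19), melanocyte markers for 2 of 4 (Slc45a2 0.32 ± 0.31, Dct -0.14 ± 0.21) and hypoxia and glycolysis genes for 6 of 10 (Bnip3 0.30 ± 0.34, Adm -0.15 ± 0.82). The sex-linked list had 1 tested member, Xist, and was not tested as a list. Without 1 array and at the preset correlation, adipocyte markers passed as higher (medians 1.08 without control 1 and 1.05 without mutant 1) or lower (-0.78 without control 2), and leukocyte, mast cell and fibroblast lists likewise passed in both directions. Schwann cell and nerve markers passed as higher without control 2 (median 0.52) and without mutant 2 (0.43). With all 4 arrays each of these 5 lists had adjusted p = 0.941 with an estimated correlation.

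**Figure D3:**
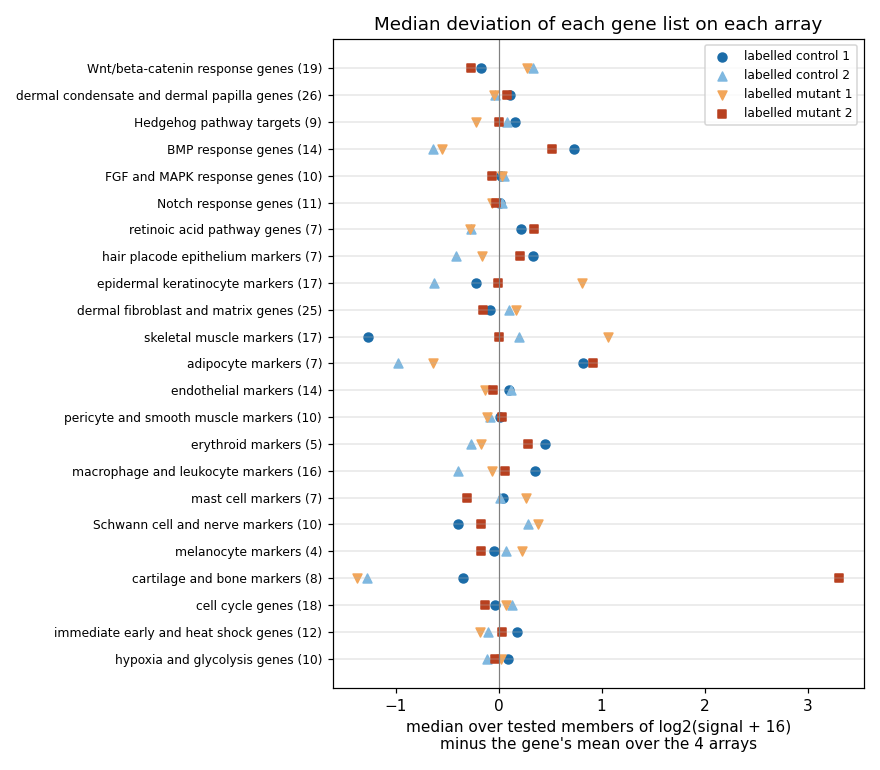
Median over the tested members of each gene list, on each of the 4 arrays, of log2(signal + 16) minus the gene's mean over the 4 arrays, with the number of tested members in parentheses. Cartilage and bone markers reach 3.31 on mutant 2, muscle markers lie at 1.06 on mutant 1 and -1.27 on control 1, and BMP response genes lie at 0.73 and 0.52 on control 1 and mutant 2 and at -0.64 and -0.55 on control 2 and mutant 1.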

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

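The crossed pairing and the methods' t-test were chosen after the data were seen. The count of probe sets past the threshold was 0 under other pseudocounts, scalings, filters and eBayes options, 0 with a paired model (replicate block), 0 to 1 without each array, and 3 by the methods' t-test at its own threshold. Same-numbered arrays deviated oppositely across probe sets (correlation -0.6163), and a crossed replicate block gave 108 (94 higher, 14 lower). Of the lists, 6 passed in the main setting, 0 with an estimated correlation, 0 with fry, 7 to 9 without each array and 9 with the crossed block. Leaving out arrays moved the share with the authors' direction from 0.654% to 99.3%, because the arrays labelled control 1 and mutant 2 resemble each other (r = 0.9814), as do control 2 and mutant 1 (r = 0.9842). Pseudocount 1 ended the cartilage call (adjusted p = 0.058), median centring the cell cycle call (0.0594), and no filter the cell cycle (0.0577) and immediate early calls (0.0593). Without each array the cartilage median ran from -0.72 to 4.30 and that of cell cycle genes from -0.17 to 0.0495, and of 72 named genes 26 changed sign and 35 more moved by over 1.5 times. Where the sign changed, log2 differences ran from -1.74 to 0.63 for Dkk1, -0.74 to 0.12 for Lef1, -1.45 to 2.72 for Rspo2, -0.62 to 1.61 for Alpl, -1.16 to 1.69 for Hhip, -0.46 to 1.96 for Bmper, -0.37 to 1.37 for Atoh8, -0.45 to 0.78 for Dll1, -0.19 to 0.66 for Dhrs3, -0.0827 to 1.25 for Bmp2, -0.10 to 3.31 for Krtdap, -0.38 to 2.97 for Lor and -0.18 to 2.27 for Mfap5. They ran from -1.40 to 4.12 for Car3, -1.89 to 4.18 for Adipoq, -0.96 to 0.20 for Hbb-y, -0.35 to 0.75 for Hbb-bh1, -0.0232 to 0.56 for Aif1, -0.51 to 0.17 for Hdc, -0.66 to 1.90 for S100b, -0.0542 to 0.69 for Slc45a2, -0.36 to 0.0857 for Dct, -0.70 to 6.53 for Col2a1, -0.39 to 0.0582 for Aurkb, -0.0601 to 0.67 for Bnip3 and -1.16 to 0.86 for Adm. With fewer arrays the lone array of a group is assumed to vary like the others. The causes of the other changes were not tested. The scan date block was not run because all arrays share a day.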

Other observations

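The tests of the following patterns were chosen after the results were seen, except the one on a second set of cartilage genes, which was set before those genes were looked at.

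Some genes of the fixed lists, outside the authors' deposited table, had signals that did not follow the labels. The adipocyte gene Adipoq gave 1301 and 1695 on the arrays labelled control 1 and mutant 2 and 3.55 and 57.6 on control 2 and mutant 1, and the lipid transporter Cd36 gave 1440, 1170, 665 and 824 in the same order. The BMP response genes Msx1 and Msx2, homeobox factors, gave 284 and 138 on control 1 and 266 and 117 on mutant 2, but 36.5 and 14.5 on control 2 and 26.9 and 15.3 on mutant 1. Wnt response genes went both ways: Axin2 and Sp5 gave 77.5 and 13.5 on control 1 and 77.4 and 13.7 on mutant 2, against 202 and 102 on control 2 and 144 and 79.7 on mutant 1. The Wnt antagonists Dkk1 and Dkk2, of the same list, gave 1584 and 790 on control 1 and 1042 and 842 on mutant 2, against 293 and 185 on control 2 and 199.8 and 206 on mutant 1. Shh, the ligand made by hair placodes, gave 66.3 and 82.5 on control 1 and mutant 2 and 15.9 and 12.4 on control 2 and mutant 1. These genes were chosen after their values were seen, and no test was run on them.

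The first pattern is that the folds of the authors' deposited table follow the arrays labelled control 1 and mutant 2. Carry-over of epidermis that expresses the epidermal list, as the source of the pattern, is argued against by the array labelled mutant 1 alone. The list was highest on mutant 1 by 0.822 over the higher of control 1 and mutant 2 (their own gap was 0.212). Krt5 and Krt14 were also highest there, at 311 and 247. Sfn went the other way, with 72.1 and 102 on control 1 and mutant 2 and 3.5 and 62.7 on control 2 and mutant 1. The list was lowest on control 2, at -0.63, against -0.22 on control 1 and -0.01 on mutant 2. A separate carry-over on mutant 1 could therefore hide a shared one and is not excluded. Epithelium that lacks these markers is not covered by the list. Spiked hybridization controls cannot decide on a fluidics or scanning effect on all probes alike, since scaling each array to a mean of 150.0 would remove it. They differed by 0.082 (log2) between the module pairs, which coincide with the pattern, and by 0.16 and 0.499 within them. The listed probe sets differed by a median size of 1.37, 97 up and 56 down. These counts repeat those of the authors' deposited table, since the module pairs coincide with the pattern, and do not decide on such an effect. The values argue against the table's folds having been taken on the arrays grouped as labelled, though GCRMA was not rerun. Both arrays labelled mutant lay on one side of both labelled control for 0 of the 153 probe sets. Differences by label lay between -0.59 and 0.50, against log2 folds from -6.64 to 10.3. An exchange of the labels of control 1 and mutant 1 cannot be told apart from a fault in the table. The exchange gives the direction of the authors' deposited table for 153 of 153 probe sets, against 80 as labelled and 69 in the remaining split. This restates the pattern on probe sets chosen from the same arrays. The exchange gave 1380 probe sets past the threshold against 0 as labelled, which points to a structure of the arrays. Exchanging the labels of control 2 and mutant 2 instead would give the same split, with the direction opposite to the authors' deposited table. Embryo stage, follicle epithelium, a module effect on some probes and a fault in the table were not tested. The hair placode list had median deviations of 0.33 on control 1 and 0.21 on mutant 2. They were -0.41 on control 2 and -0.16 on mutant 1, so the list followed the split, though its members Madcam1 and Lama5 went the other way. A pairing of the arrays by stage, follicle epithelium or module would not alone set the table's groups against the labels.

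The second pattern is that cartilage genes were high on the array labelled mutant 2. If the labels hold, an effect of the mutation alike on both arrays labelled mutant is argued against. On both of them, 0 of 8 tested list members lay above both controls, and the list's median deviation on mutant 1, -1.38, was the lowest of the 4 arrays. Comp, Cnmd and Col11a2, named for lying above both controls on both, did so on mutant 1 by little (19.1, 48.0 and 23.7 against control 2 at 14.1, 45.4 and 18.5). An effect in 1 embryo stays open. Cartilage in that one dissection may account for the pattern. Of a second set of 11 cartilage genes, all 11 had their highest signal on mutant 2, 6 of them bright enough to be tested. Examples are Col9a3 at 1032 against 53.0 or less and Epyc at 912.8 against 32.5 or less. Sox5 (24.7 against 20.6 or less) and Sox6 (75.4 against 54.3 or less) differed little. An effect in 1 embryo could raise these genes alike, so the second set does not tell it from dissected cartilage. The bone genes Sp7 (288 on control 1 and 275 on mutant 2) and Ibsp (190 and 1365) were above control 2 (52.9 and 8.0) and mutant 1 (45.0 and 17.0) on both. So were the cartilage genes Col11a1 (380 and 1672, against 116 and 122) and Matn4 (108 and 350, against 27.0 and 3.1). Acan was so by little on control 1 (19.2 against 16.6 on mutant 1), while Col2a1, Col9a1 and Matn1 were not. Of the second set, Col9a2 was so (61.4 and 323, against 14.9 and 13.1). Epyc was so at low signal on control 1 (32.5 against 9.0 and 6.9), while Col9a3 and Sox6 were not. Cartilage in 1 dissection leaves Sp7, Ibsp, Col11a1, Matn4 and Col9a2 unaccounted for. Were the labels of control 1 and mutant 1 exchanged, an effect of the mutation would stay open for them.

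The third pattern is that muscle markers were higher on the arrays labelled mutant. The list's median differed by 1.463 (log2) between the arrays labelled control 1 and control 2, more than the 1.08 between labels. Muscle that varies between dissections may therefore account for the pattern. The median deviation was -1.27 on control 1 and 0.0075 on mutant 2, below 0.19 on control 2 and 1.06 on mutant 1. The list thus also followed the split of the first pattern, though mutant 2 and control 2 lay close. An effect of the mutation as labelled cannot be told apart from varying muscle or from that split. Of 17 members, 2 lay above both controls on both mutant arrays, and the median fell to 0.28 without control 1.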
